A study of Homo sapiens with 6 samples.

How the data were processed

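Total RNA of MDA-MB-231 cells was amplified with a 3' in vitro transcription kit, labelled with biotin and hybridized to Affymetrix PrimeView arrays, per the labels' protocols. Groups and replicate numbers were taken from the labels, which give 3 DMSO and 3 SAHA samples, each at 8 h, with SAHA at 5 µM. The deposited values are log2 expression values per probe set, and RMA is named in the submitters' processing notes. RMA corrects background, makes the arrays' distributions equal by quantile normalization and summarizes probes by median polish. The software and its version are not given in the sources used here. In the deposited table the sorted columns differed from their mean by at most 0.0936, and values ran from 2.33 to 14.33. Because RMA makes distributions equal, a shift of most transcripts in one direction cannot be read from these values. A fold change is understated where a probe set lies near the floor of the scale.

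The table held 49395 probe sets, of which 102 were array controls. Gene names came from the platform's annotation, with symbols looked up through Entrez identifiers in a RefSeq gene table of assembly GRCh38.p14. No symbol needed updating, and 27 probe sets had an identifier not matched there. Of the other probe sets, 44988 named 1 gene, 1832 several and 2473 none. Genomic positions are not given, because the sources used here name no build for the probes. A gene was represented by the probe set with the highest mean over the 6 arrays among those that name only that gene, which gave 18132 genes, 11734 of them with several probe sets. Of the 5476 genes with 2 or more probe sets called, 161 (2.94%) had probe sets called in both directions, so a gene's value is that of 1 probe set. Of the named genes, 32 moved by more than 1.5-fold with the mean or the second brightest of their probe sets or without _x_at and _s_at probe sets, and such values are given beside them. Probe sets whose names end in _x_at or _s_at hold probes that match similar transcripts, called here probe sets shared by similar transcripts.

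Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without trend or robust moderation, as SAHA minus DMSO over all 6 arrays, without covariates or a filter on level. The test was two-sided with Benjamini-Hochberg adjustment over all genes, at 0.05. Counts at 2-fold took genes past that threshold with a log2 fold change of at least 1 in size. For genes named in the text, values are means of log2 values with SD, and log2 fold changes with limma's moderated standard error. For a second probe set, the standard error and adjusted p come from the same test over all probe sets. The 31 gene lists, written from textbook knowledge, hold 712 genes, of which 657 were measured and 55 were not analysed here. Each list with at least 5 measured genes was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The estimated form works with the 4 residual degrees of freedom of this design.

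The groups, the test, the gene lists, the alternatives listed next and the rule for naming genes were set before the data were examined. The rule takes the 12 largest rises and 12 largest falls among changed genes whose groups do not overlap and whose symbol is not a placeholder. In each list it takes the 4 members with the smallest p and the 2 with the smallest p among called members that moved against most of the list. It also takes each measured HDAC gene and CDKN1A. Alternatives were the replicate number as a block, the mean or the second of a gene's probe sets, filters at mean log2 values of 5 and 7, leaving out _x_at and _s_at probe sets, and quantile normalization once more. Others were centring on ribosomal protein genes or hybridization spike-ins, trend and robust moderation, array weights, leaving out each array, a threshold of 0.01, limma's treat at 1.2-fold and 2-fold, an ordinary test per gene, and probe sets in place of genes. Centring on poly-A spike-ins and the ACTB 3' to 5' difference as a covariate were added after the data were seen.

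Array controls were compared with two-sided exact permutation tests, which cannot go below 0.1 with 3 arrays against 3. The procedure was first tested on simulated data with the real genes' levels. With 50 genes changed at each size among 18132, it recovered 8% at 1.2-fold, 68% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 8 false calls. In simulated lists camera called the 1 shifted list and 0 of 30 unshifted ones. The simulated genes varied independently, so this says nothing of lists whose genes vary together. Far fewer genes changed in the simulation than in the data, which made its adjusted threshold stricter. Figures were drawn with matplotlib 3.10.9. Probe sets that name several genes or none were left out of the gene-level tests.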

Results

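Gene expression was measured on 6 Affymetrix PrimeView arrays in MDA-MB-231 cells, a triple-negative human breast cancer line with mesenchymal features. The cells had been kept for 8 h with 5 µM SAHA (vorinostat), an inhibitor of class I, II and IV histone deacetylases (HDACs), or with its solvent DMSO, with 3 arrays per group. The question addressed is which transcripts differ after 8 h of HDAC inhibition. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which can be technical. The number of arrays, 3 per group, limits the precision of each value.

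Arrays of one group were nearly alike. Over all probe sets that are not controls, Pearson's r across probe sets was 0.997 for each pair of DMSO arrays and 0.998 for each pair of SAHA arrays, against 0.968 to 0.970 between groups. The first principal component held 89.2% of the variance and separated the groups. Among the array controls, the difference between the 3' and 5' probe sets of ACTB, a measure of transcript integrity and amplification, was 0.89 ± 0.16 log2 units in DMSO and 0.61 ± 0.06 in SAHA arrays (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). It separated the groups and so goes with every gene group described here. The same difference for GAPDH was far smaller and went the other way, at 0.03 ± 0.02 in DMSO and 0.06 ± 0.02 in SAHA arrays (exact permutation p = 0.1). A 28S rRNA control was at 10.49 ± 0.11 in DMSO and 9.97 ± 0.04 in SAHA arrays (exact permutation p = 0.1). The hybridization spike-ins were level, at 10.48 ± 0.05 and 10.48 ± 0.04 (exact permutation p = 1), and the poly-A spike-ins were at 6.67 ± 0.11 and 6.51 ± 0.08 (exact permutation p = 0.2). With Benjamini-Hochberg adjustment over the 8 control measures, the p-values of these measures lay between 0.133 and 1.

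With SAHA the transcripts of nearly every second gene on the array differed from DMSO. The largest rise was that of CCL20, a chemokine that attracts lymphocytes and dendritic cells, at 168-fold. The largest fall was that of HMGA2, an architectural chromatin protein, from a log2 value of 9.87 to 5.47 in its brightest probe set. With the mean of its probe sets its log2 fold change was -1.32. Genes of cholesterol synthesis, inflammation, the lysosome and cell cycle inhibition were mostly higher. Genes of ribosome synthesis, S phase and survival from apoptosis were mostly lower. Values below are log2 fold changes of SAHA over DMSO with their standard error, from limma with n = 3 arrays per group, and adjusted p-values are over all 18132 genes unless a list is named.

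In limma's test 8764 genes (48.3%) changed, of which 4457 were higher and 4307 lower with SAHA. Of these, 1075 were higher and 810 lower by at least 2-fold. The 3 SAHA values lay beyond the 3 DMSO values in 8725 of the changed genes, and in 55.5% of all genes, where chance gives 10%. The share called depends on level. Under a mean log2 value of 4, 4.19% of genes were higher and 4.52% lower, and at 8 to 9 the shares were 37.7% and 40.2%. Many called members in a list of well expressed genes are therefore not by themselves a trait of that list. The balance of rises and falls depends on the scaling. Centred on ribosomal protein genes, which shifts the median of all genes by 0.10, 5753 genes were higher and 3473 lower. Centred on poly-A spike-ins, a scaling chosen after the data were seen, the shift was 0.16, with 5829 genes higher and 2556 lower.

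CCL20 rose by 7.39 ± 0.13 (adjusted p = 8.52e-08), from a log2 value of 5.40 ± 0.28 in DMSO to 12.80 ± 0.05 in SAHA arrays (SD, n = 3). DHRS2, a mitochondrial short-chain dehydrogenase, rose by 5.77 ± 0.10, from 5.19 ± 0.14 to 10.96 ± 0.13. Next in the gene-level test came CRISPLD2, a secreted glycoprotein, at 4.99 ± 0.09, the small GTPase ARL14 at 4.97 ± 0.18 and the ETS-family repressor ETV7 at 4.43 ± 0.17. A probe set of RASA4 ending in _x_at rose by more than CRISPLD2, by 5.26 ± 0.12 (adjusted p = 1.45e-07 in limma's test over probe sets). Its annotation repeats the symbol, so it was counted among probe sets that name several genes and is not ranked here. FAM117A rose by 4.21 ± 0.11, ID2, an inhibitor of basic helix-loop-helix transcription factors, by 4.13 ± 0.11 and TPPP, which promotes tubulin polymerization, by 4.12 ± 0.14. The 12 largest rises were completed by the surface glycoprotein CD24 (4.05 ± 0.12), the poly(A) polymerase TENT5C (3.92 ± 0.13), the focal adhesion scaffold NEDD9 (3.90 ± 0.14) and the secretory granule protein SCG2 (3.85 ± 0.11). ID2 and CD24 were measured only by probe sets shared by similar transcripts. Other choices of probe sets moved 6 of the 12 rises by more than 1.5-fold. With the second brightest probe set CRISPLD2 was at 1.67, ETV7 at 5.74, FAM117A at 1.11, TPPP at 2.94, TENT5C at 3.01 and NEDD9 at 2.63, and with the mean of its probe sets ETV7 was at 1.43, CRISPLD2 at 1.80 and NEDD9 at 2.01. In DMSO, 11 of these 12 genes were under a log2 value of 6, and CRISPLD2 was at 6.80 ± 0.16.

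HMGA2 fell by 4.39 ± 0.08 (adjusted p = 8.52e-08), from 9.87 ± 0.06 to 5.47 ± 0.13. Its probe set with the second highest mean gave -0.05 ± 0.11 (adjusted p = 0.742 over probe sets), at a mean log2 value of 5.97. Its dimmer probe sets gave -1.26 ± 0.11, -1.41 ± 0.15, -0.44 ± 0.16 (adjusted p = 0.0600 over probe sets) and -0.37 ± 0.12, the rest with an adjusted p under 0.05. With the mean of all its probe sets HMGA2 was at -1.32. PRDM8, a zinc finger protein, was at -3.64 ± 0.09, the adhesion molecule AMIGO2 at -3.53 ± 0.07, the RAB5 exchange factor RIN2 at -3.49 ± 0.08 and ZNF804A at -3.46 ± 0.14. KCTD4 was at -3.45 ± 0.12 and VEGFC, a growth factor of lymphatic vessels, at -3.45 ± 0.06. BCAR3, an adaptor in integrin signalling, was at -3.29 ± 0.10, ITPRIPL2 at -3.17 ± 0.06, the epoxide hydrolase EPHX4 at -3.11 ± 0.07 and the presynaptic protein RIMS2 at -3.10 ± 0.06. With the second brightest probe set PRDM8 was at -2.45 and KCTD4 at -1.55, and with the mean of its probe sets ITPRIPL2 was at -2.37. The metalloprotease ADAMTS6 was at -3.24 ± 0.10 in its brighter probe set, while its other, dimmer one gave 0.11 ± 0.12 (adjusted p = 0.510 over probe sets).

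**Figure D1:**
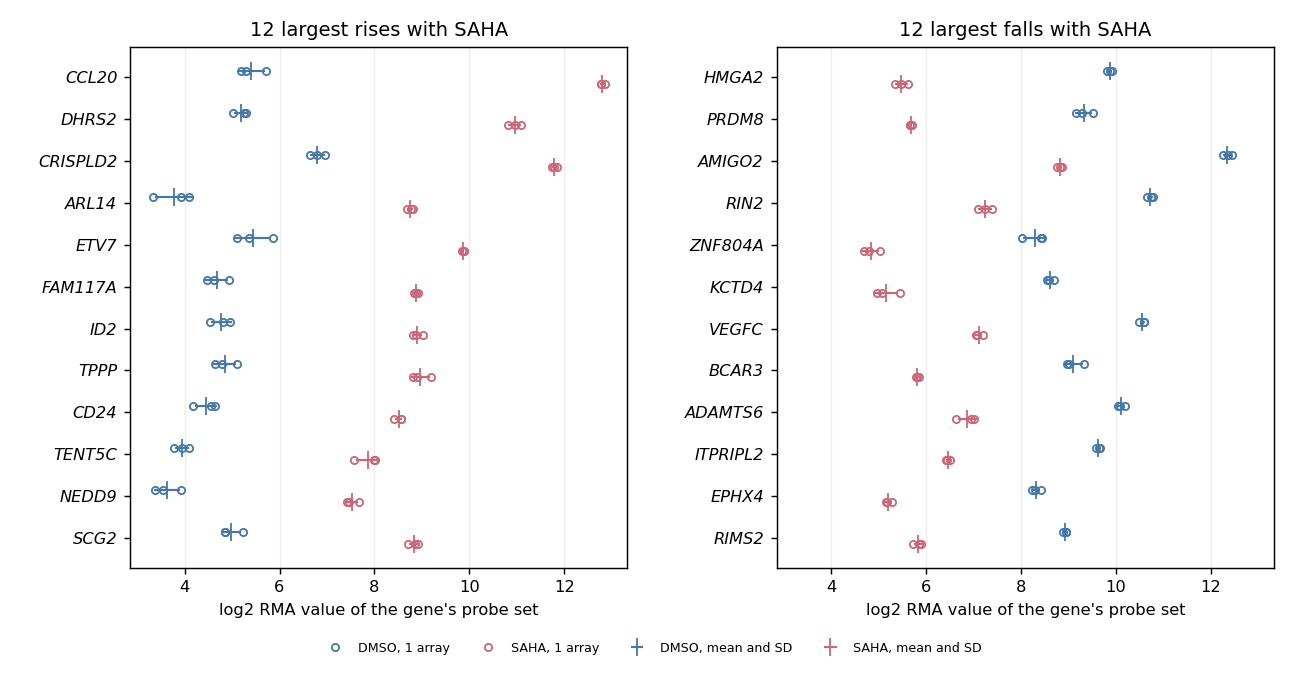
Log2 RMA values (horizontal axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), with 1 open circle per array, and a bar and line for the mean and SD of the 3 arrays of a group. The 3 SAHA arrays lie beyond the 3 DMSO arrays for each of the 24 genes, from CCL20 at 5.40 and 12.80 to RIMS2 at 8.93 and 5.82.

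CDKN1A, which encodes the cell cycle inhibitor p21 and is the usual marker gene of HDAC inhibition, rose by 1.91 ± 0.05 (3.76-fold, adjusted p = 2.08e-07). Its log2 values were 9.73, 9.72 and 9.71 in the DMSO arrays and 11.63, 11.66 and 11.60 in the SAHA arrays. Of 12 measured genes often raised by HDAC inhibitors in other cells, 11 rose and 1 fell, and 12 changed when adjusted over the list alone. SAT1, of polyamine breakdown, rose by 2.76 ± 0.07, the metallothionein MT1X by 1.87 ± 0.05 and the secreted chaperone CLU by 2.90 ± 0.09. A second, dim probe set of CLU gave 0.20 ± 0.13 (adjusted p = 0.275 over probe sets). KLF6, a transcription factor, fell by 0.40 ± 0.06, a call that did not pass after centring on poly-A spike-ins. The list was past the threshold in limma's camera test with a preset correlation (adjusted p = 7.76e-06), and had an adjusted p = 0.0969 with an estimated correlation.

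Of 11 genes often lowered by HDAC inhibitors in other cells, 7 fell and 2 rose, and 9 changed when adjusted over the list alone (camera adjusted p = 0.0302, and adjusted p = 0.134 with an estimated correlation). Without genes under a mean log2 value of 5 or of 7, the list did not pass. CCND1, the G1 cyclin, fell by 2.19 ± 0.06, CTPS1, of CTP synthesis, by 1.77 ± 0.06 and TYMS, of thymidylate synthesis, by 0.85 ± 0.06. HMGCS1, of cholesterol synthesis, rose by 1.68 ± 0.07 and the transcription factor MYC by 0.38 ± 0.05.

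Among the 11 HDAC genes themselves, 4 rose and 2 fell, and 6 changed when adjusted over the list alone (camera adjusted p = 0.302, and adjusted p = 0.461 with an estimated correlation). HDAC11 rose by 2.02 ± 0.05, HDAC5 by 1.60 ± 0.13, HDAC3 by 0.94 ± 0.06 and HDAC1 by 0.33 ± 0.05. HDAC9 fell by 1.06 ± 0.08 and HDAC8 by 0.36 ± 0.10. HDAC5 was at 0.65 in its second brightest probe set. The rise of HDAC11 was smaller in its other 4 probe sets, at 0.22 to 0.40, of which 2 had an adjusted p under 0.05. HDAC8 had 2 probe sets called lower and 1 called higher, and its fall did not pass with the mean of its probe sets or after centring on poly-A spike-ins. HDAC7 did not pass in the probe set used, at -0.05 ± 0.08, while its other 5 probe sets gave -0.41 to -1.45, each with an adjusted p under 0.05 over probe sets. HDAC2 at -0.05, HDAC4 at 0.04, HDAC6 at 0.11 and HDAC10 at 0.04 did not pass either.

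Chromatin genes moved both ways. Of 16 measured histone genes with polyadenylated transcripts, 10 rose and 2 fell, and 12 changed when adjusted over the list alone (camera adjusted p = 0.00755, and adjusted p = 0.116 with an estimated correlation). H2BC5 rose by 1.89 ± 0.06, H2AJ by 1.66 ± 0.10 and H2AC6 by 1.28 ± 0.07, while the variants MACROH2A1 (-0.29 ± 0.05) and H2AZ1 (-0.20 ± 0.05) fell, calls that did not pass after centring on poly-A spike-ins. The linker histone H1-10 rose by 2.12 ± 0.07, in a probe set shared in design by similar transcripts, while its other probe set gave 0.35 ± 0.14 (adjusted p = 0.0669 over probe sets). Without such probe sets the histone list had an adjusted p = 0.0644.

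Of 29 chromatin enzymes and bromodomain proteins, 16 fell and 6 rose, and 22 changed when adjusted over the list alone (camera adjusted p = 0.0320, and adjusted p = 0.278 with an estimated correlation). The methyltransferase SETD7 fell by 1.68 ± 0.05, the DNA methyltransferase DNMT3A by 1.11 ± 0.06, the acetyltransferase KAT5 by 1.13 ± 0.07 and MTA1, of the NuRD complex, by 0.99 ± 0.06. DNMT3B rose by 1.33 ± 0.08 and the demethylase KDM5B by 1.13 ± 0.07. The list did not pass in 5 other settings, among them the mean of a gene's probe sets, and centred on poly-A spike-ins 11 members were lower and 7 higher (median -0.07).

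Cell cycle inhibitors were mostly higher and genes of DNA replication mostly lower. Of 14 measured cell cycle inhibitors, 9 rose and 2 fell, and 11 changed when adjusted over the list alone (camera adjusted p = 0.00360, and adjusted p = 0.116 with an estimated correlation). CDKN1C, which encodes p57, rose by 3.39 ± 0.09 (10.5-fold), and CDKN2D, which encodes p19, by 1.78 ± 0.06. BTG1, an antiproliferative factor, rose by 0.92 ± 0.05 and was at 0.06 ± 0.08 in its dim probe set, the only one not shared by similar transcripts. CDKN1B, which encodes p27, fell by 0.50 ± 0.08 and RBL2, a relative of the retinoblastoma protein, by 0.26 ± 0.06. These calls did not pass with the ACTB difference as a covariate. Over all other settings CDKN1B stayed between -0.55 and -0.33 and RBL2 between -0.29 and -0.09. The call of RBL2 was lost in 4 of 19 other settings, among them centring on poly-A spike-ins and its second brightest probe set (-0.15 ± 0.10).

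Of 41 S phase genes, 25 fell and 6 rose, and 32 changed when adjusted over the list alone (camera adjusted p = 0.000372, and adjusted p = 0.0969 with an estimated correlation). CDCA7 fell by 1.48 ± 0.06, UHRF1, which maintains DNA methylation, by 1.03 ± 0.05, and the uracil glycosylase UNG by 0.99 ± 0.06. The ribonucleotide reductase subunit RRM2 (0.54 ± 0.05) and the histone mRNA binding protein SLBP (0.47 ± 0.06) rose. Of 52 genes of G2 and mitosis, 29 fell and 8 rose, and 37 changed when adjusted over the list alone (camera adjusted p = 0.00225, and adjusted p = 0.133 with an estimated correlation). The falls were 25 centred on ribosomal protein genes and 23 (median -0.09) on poly-A spike-ins. The mitotic kinase AURKA fell by 1.13 ± 0.06 and TMPO, a protein of the nuclear lamina, by 1.68 ± 0.09. The kinase NEK2 rose by 0.86 ± 0.05 and CDCA2 by 0.77 ± 0.05.

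Survival genes mostly fell. Of 10 measured anti-apoptotic genes, 9 fell and 1 rose, and 10 changed when adjusted over the list alone (camera adjusted p = 0.000372, and adjusted p = 0.116 with an estimated correlation). CFLAR, an inhibitor of caspase 8 activation, fell by 1.85 ± 0.05, BCL2L1, which encodes BCL-XL, by 1.46 ± 0.07, BCL2 by 1.35 ± 0.09 and the caspase inhibitor XIAP by 0.76 ± 0.05. With the mean of their probe sets CFLAR was at -0.91 and BCL2 at -0.67. MCL1 rose by 0.29 ± 0.05. Of 19 pro-apoptotic genes, 11 rose and 5 fell, and 16 changed when adjusted over the list alone (camera adjusted p = 0.0915, and adjusted p = 0.189 with an estimated correlation). The TRAIL receptor TNFRSF10B rose by 1.18 ± 0.05, CASP9 by 1.27 ± 0.07 and BNIP3L by 1.26 ± 0.07. The other TRAIL receptor, TNFRSF10A, fell by 1.16 ± 0.08 and BID by 1.13 ± 0.06.

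Ribosome synthesis gave the smallest list p-value in camera with a preset correlation, though not with an estimated one or in fry. Of 34 measured genes of ribosome synthesis in the nucleolus, 26 fell and 3 rose, and 29 changed when adjusted over the list alone (camera adjusted p = 5.37e-07, and adjusted p = 0.133 with an estimated correlation). RRS1, a ribosome assembly factor, fell by 1.56 ± 0.06, GAR1, of the box H/ACA particles that guide pseudouridylation, by 1.43 ± 0.06, WDR43 by 1.29 ± 0.05 and NOP16 by 1.28 ± 0.06. RRP9, of the U3 particle, rose by 0.84 ± 0.07 and POLR1F, of RNA polymerase I, by 0.37 ± 0.06, a call lost in 1 of 19 other settings. The listed cytosolic ribosomal proteins moved little by comparison. Of 48 measured, 11 fell and 0 rose in limma's test, and 1 changed when adjusted over the list alone (camera adjusted p = 0.00442, and adjusted p = 0.133 with an estimated correlation). Their median was -0.10, with RPL13 at -0.47 ± 0.06, RPL6 at -0.24 ± 0.05, RPL4 at -0.22 ± 0.06 and RPL29 at -0.21 ± 0.05. The call of RPL4 was lost in 7 of 19 other settings, and those of RPL6 and RPL29 in 3 of 18 each. Centred on poly-A spike-ins, that median was 0.06 and 1 member was lower, and the list did not pass. The list's mean relative to all genes, which centring cannot move, was -0.14. RPL27A, a cytosolic ribosomal protein that the list leaves out, fell by 1.99 ± 0.11 (limma's adjusted p = 3.07e-06). Of all 51 genes with RPL symbols, 18 were lower and 1 higher.

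Inflammatory genes were mostly higher. Of 24 measured genes of the inflammatory and NF-kB response, 17 rose and 5 fell, and 22 changed when adjusted over the list alone (camera adjusted p = 0.00193, and adjusted p = 0.116 with an estimated correlation). Beside CCL20, the adhesion receptor ICAM1 rose by 2.65 ± 0.06. The NF-kB subunit gene NFKB1 fell by 2.17 ± 0.05 and LIF, a cytokine of the interleukin 6 family, by 2.24 ± 0.06 (-1.39 in its second brightest probe set). Interferon response genes moved both ways, with 8 of 21 higher, 4 lower, and 13 changed when adjusted over the list alone (camera adjusted p = 0.265, and adjusted p = 0.318 with an estimated correlation). IFIT1 rose by 2.96 ± 0.05, OASL by 2.43 ± 0.06, ISG15 by 2.09 ± 0.05 and IFI6 by 1.72 ± 0.06, while IFIT2 fell by 2.01 ± 0.11 (-0.84 in its other probe set) and IFIT3 by 1.99 ± 0.13. Over the genes with a mean log2 value of 7 or more, the interferon list passed (camera adjusted p = 0.0250). That filter left out IFIT2 and IFIT3, at means of 5.33 and 6.73, and kept IFIT1, OASL, ISG15 and IFI6.

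Of 24 antigen presentation genes, 12 rose and 4 fell, and 17 changed when adjusted over the list alone (camera adjusted p = 0.0169, and adjusted p = 0.134 with an estimated correlation). The stress-induced ligands of the NKG2D receptor MICA (1.54 ± 0.06) and MICB (0.88 ± 0.05) rose, as did HLA-DMA, of class II peptide loading, by 1.74 ± 0.11. ULBP2, another such ligand, rose by 1.58 ± 0.10 in 1 probe set, while its other 2, both near the floor of the scale, gave -0.10 ± 0.18 and -0.07 ± 0.09. The peptide transporter subunit TAP2 fell by 0.80 ± 0.05 and the immunoproteasome subunit PSMB10 by 0.78 ± 0.06. The list did not pass without genes under a mean of 7 or without probe sets shared by similar transcripts.

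Of 24 immediate early genes, 16 rose and 5 fell, and 21 changed when adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.116 with an estimated correlation). The phosphatases DUSP1 (2.35 ± 0.08) and DUSP5 (1.63 ± 0.07) and the mRNA decay factor ZFP36 (2.04 ± 0.07) rose. FOSL1, a FOS-family transcription factor, fell by 1.76 ± 0.06 and the phosphatase DUSP4 by 1.32 ± 0.06. Without probe sets shared by similar transcripts the list had an adjusted p = 0.0524. Metallothioneins, which bind zinc and copper, rose in 6 of 8 and fell in 0 in limma's test, with 7 changed when adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.116 with an estimated correlation). Beside MT1X, MT1F rose by 1.85 ± 0.08, MT3 by 1.02 ± 0.07 and MT1E by 0.29 ± 0.07. The call of MT1E did not pass with the ACTB difference as a covariate, while its value stayed between 0.25 and 0.45 over all other settings. In the second brightest probe set MT1F was at 0.97 and MT3 at 0.38, and MT1F was measured only by probe sets shared by similar transcripts.

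Cholesterol synthesis genes rose in 14 of 17 and fell in 2, and 16 changed when adjusted over the list alone (camera adjusted p = 0.000138, and adjusted p = 0.0969 with an estimated correlation). INSIG1, a feedback regulator of sterol synthesis, rose by 2.15 ± 0.09, TM7SF2 by 1.26 ± 0.07 and MSMO1 by 1.04 ± 0.05, beside HMGCS1. FDPS (-0.36 ± 0.06) and EBP (-0.19 ± 0.06) fell, calls that did not pass after centring on poly-A spike-ins and, for EBP, in 9 of 19 other settings. Lysosome and autophagy genes rose in 15 of 22 and fell in 5, and 20 changed when adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.116 with an estimated correlation). The sialidase NEU1 rose by 2.23 ± 0.08, the autophagy protease ATG4A by 1.48 ± 0.07, WIPI1 by 1.48 ± 0.05 and MAP1LC3B, of the autophagosome membrane, by 1.08 ± 0.05. ATG7 (-0.40 ± 0.06) and HEXA (-0.30 ± 0.05) fell, which did not pass after centring on poly-A spike-ins. In the 3 HEXA probe sets not shared by similar transcripts the values were -0.03 ± 0.08, -0.05 ± 0.08 and -0.44 ± 0.12.

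Stress genes moved both ways. Of 22 genes of the unfolded protein and amino acid stress responses, 13 rose and 7 fell, and 20 changed when adjusted over the list alone (camera adjusted p = 0.195, and adjusted p = 0.274 with an estimated correlation). SESN2 rose by 1.98 ± 0.05 and DDIT4 by 2.36 ± 0.09, both inhibitors of mTORC1 signalling, while ATF5 fell by 2.21 ± 0.07 and the pseudokinase TRIB3 by 1.31 ± 0.06 (-1.04 and -0.56 in their second brightest probe sets). Of 21 heat shock and protein folding genes, 8 rose and 6 fell, and 16 changed when adjusted over the list alone (camera adjusted p = 0.518, and adjusted p = 0.534 with an estimated correlation). The cochaperones DNAJB1 (2.12 ± 0.05) and DNAJB4 (0.97 ± 0.08) and the chaperones HSPA1B (0.94 ± 0.06) and HSPA5 (0.90 ± 0.05) rose. A probe set that names both HSPA1A and HSPA1B, left out of the gene-level test, rose by 3.18 ± 0.09 (adjusted p = 3.15e-07 in limma's test over probe sets). The mitochondrial chaperones HSPA9 (-0.51 ± 0.06) and HSPE1 (-0.41 ± 0.07) fell, the latter not after centring on poly-A spike-ins, where 9 members were higher and 1 lower.

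Epithelial and mesenchymal genes moved both ways, and neither list passed in camera, whereas fry called the epithelial list upward (adjusted p = 4.68e-05) and the mesenchymal list downward (adjusted p = 0.0104). Of 30 epithelial genes, 11 rose and 6 fell, and 17 changed when adjusted over the list alone (camera adjusted p = 0.297, and adjusted p = 0.321 with an estimated correlation). The transcription factors GRHL1 (3.56 ± 0.08, 11.8-fold) and ELF3 (3.43 ± 0.14, 10.7-fold) and the keratin KRT19 (2.74 ± 0.08) rose. EPCAM fell by 0.93 ± 0.06 and the desmosomal protein PKP3 by 1.14 ± 0.10 in the brighter of its 2 probe sets (-0.35 ± 0.14 in the other). GRHL1 was at 1.92 in its second brightest probe set and ELF3 at 2.73 with the mean of its probe sets, all of them shared by similar transcripts. Of 28 mesenchymal genes, 11 fell and 7 rose, and 18 changed when adjusted over the list alone (camera adjusted p = 0.523, and adjusted p = 0.534 with an estimated correlation). The excess of falls depends on the scaling, with 8 higher and 9 lower (median 0.03) centred on ribosomal protein genes, and 9 higher and 7 lower (median 0.09) on poly-A spike-ins. The transcription factor SNAI1 rose by 2.22 ± 0.07 and the collagen COL5A1 by 1.08 ± 0.07, while the membrane protease MMP14 fell by 1.78 ± 0.06 and TGFBI by 1.13 ± 0.06. Of 30 genes of adhesion, migration and invasion, 14 rose and 7 fell, and 23 changed when adjusted over the list alone (camera adjusted p = 0.315, and adjusted p = 0.485 with an estimated correlation). The urokinase PLAU fell by 2.65 ± 0.07 (6.26-fold) and its receptor PLAUR by 2.47 ± 0.07 (5.55-fold), while ANGPTL4, a secreted lipase inhibitor, rose by 1.99 ± 0.07.

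Of 18 oestrogen receptor and luminal genes, 5 rose and 6 fell, and 11 changed when adjusted over the list alone (camera adjusted p = 0.976, and adjusted p = 0.976 with an estimated correlation). AGR2 rose by 1.46 ± 0.09 (0.81 in its second brightest probe set), and the transcription factors GATA3 (-1.23 ± 0.08) and XBP1 (-1.16 ± 0.07) fell. Of 34 neuronal genes, 8 rose, each by at least 2-fold, and 3 fell, and 8 changed when adjusted over the list alone (camera adjusted p = 0.0639, and adjusted p = 0.176 with an estimated correlation). Centred on ribosomal protein genes 9 were higher and 0 lower, and on poly-A spike-ins 13 and 0. Beside SCG2, the microtubule-associated protein MAP2 rose by 3.80 ± 0.12, from a low 3.57 ± 0.23 in DMSO, and by 0.99 in its second brightest probe set. Also higher were the tubulin TUBB3 (1.55 ± 0.05) and the enolase ENO2 (1.13 ± 0.05). CHGA (-0.18 ± 0.06) and SCG5 (-0.33 ± 0.11) fell, calls lost in 14 of 17 and 8 of 18 other settings. The neuronal list did pass in 9 other settings, among them centring on ribosomal protein genes (adjusted p = 0.0495) and on poly-A spike-ins (adjusted p = 0.0106).

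Of 23 genes of homologous recombination and the DNA damage response, 10 fell and 6 rose, and 17 changed when adjusted over the list alone (camera adjusted p = 0.389, and adjusted p = 0.596 with an estimated correlation). The excess of falls depends on the scaling, with 9 higher and 9 lower centred on ribosomal protein genes, and 6 higher and 7 lower (median 0.03) on poly-A spike-ins. NBN, of the MRN complex, fell from 10.58 ± 0.08 to 9.38 ± 0.03 (SD), FANCI by 0.60 ± 0.06 and BARD1 by 0.58 ± 0.06. RAD51C rose by 0.74 ± 0.05, and the kinase CHEK2 rose by 0.64 ± 0.06 in its brighter probe set and was at 0.07 ± 0.07 in the other. Of 15 cancer-testis genes, 1 rose, the nucleosome assembly protein relative TSPYL5 by 0.82 ± 0.05, and 1 changed when adjusted over the list alone (camera adjusted p = 0.940, and adjusted p = 0.939 with an estimated correlation). The list's median was -0.06 and its mean 0.0018, and the test gave a downward direction. The median was 0.04 centred on ribosomal protein genes and 0.10 on poly-A spike-ins. SYCP1 at -0.18 ± 0.07, MAGEB2 at 0.16 ± 0.06 and SYCP3 at -0.11 ± 0.08 did not pass.

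Most markers of other cell types did not pass. Of 10 fibroblast markers, 3 rose and 0 fell in limma's test, with 3 changed when adjusted over the list alone (camera adjusted p = 0.161, and adjusted p = 0.274 with an estimated correlation). Centred on ribosomal protein genes or poly-A spike-ins 6 rose and 0 fell, and fry called the list upward (adjusted p = 0.00227). PDGFRB (0.51 ± 0.08) and COL1A1 (0.50 ± 0.09) stayed under a log2 value of 6, and in the next probe set they were at 0.03 ± 0.10 and 1.58. PDGFRA (0.26 ± 0.08) was at -0.18 ± 0.07 in its next probe set and lost its call in 10 of 17 other settings. Of 12 blood cell markers, CD14 rose by 1.01 ± 0.09, to 4.97 ± 0.04, and CD68 (-0.24 ± 0.06) and CD3E (-0.25 ± 0.07) fell, calls lost in 4 of 18 and 11 of 17 other settings, and 3 changed when adjusted over the list alone (camera adjusted p = 0.946, and adjusted p = 0.976 with an estimated correlation). Centred on poly-A spike-ins, 3 blood cell markers were higher and 0 lower. None of the 9 endothelial markers passed in limma's test, nor when adjusted over the list alone, with VWF at 0.29 ± 0.13, KDR at 0.24 ± 0.12, ERG at 0.13 ± 0.12 and CLDN5 at 0.04 ± 0.07 (camera adjusted p = 0.621, and adjusted p = 0.789 with an estimated correlation).

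**Figure D2:**
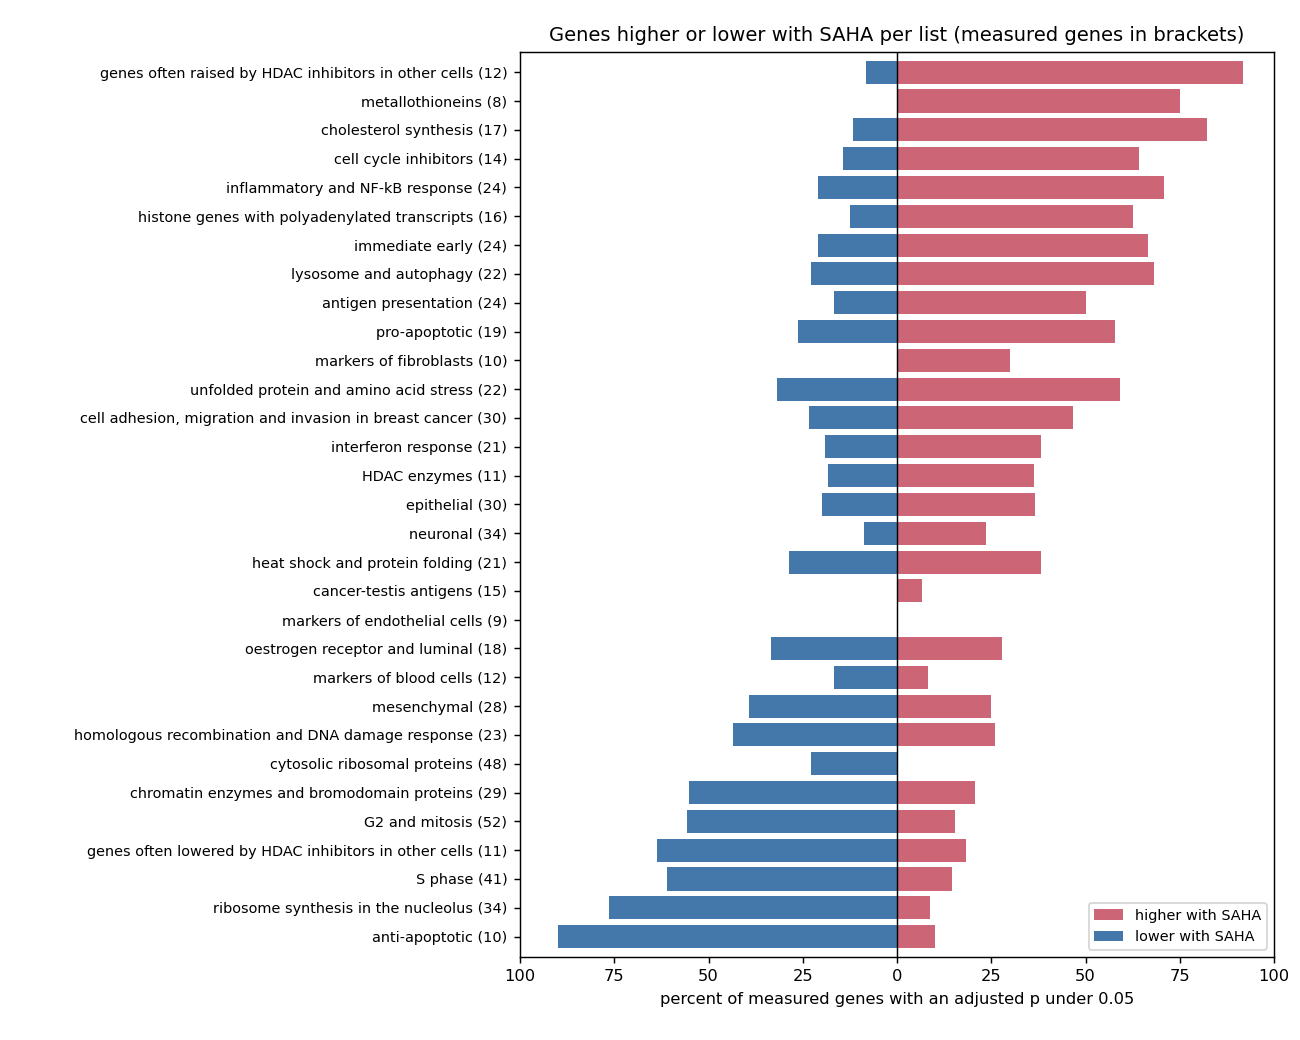
Percent of the measured genes of each of the 31 lists that were higher (red, to the right of 0) or lower (blue, to the left) with SAHA at an adjusted p under 0.05 in limma's test, with the number measured in brackets. The lists run from genes often raised by HDAC inhibitors, with 11 of 12 higher, to anti-apoptotic genes, with 9 of 10 lower.

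In camera with a preset correlation of 0.01 between genes, 16 of the 31 lists passed, 9 upward and 7 downward. With the correlation estimated from the residuals 0 passed, and 10 had an unadjusted p under 0.05, whereas limma's fry, which asks only whether a list's genes move one way on balance, called 28.

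**Figure D3:**
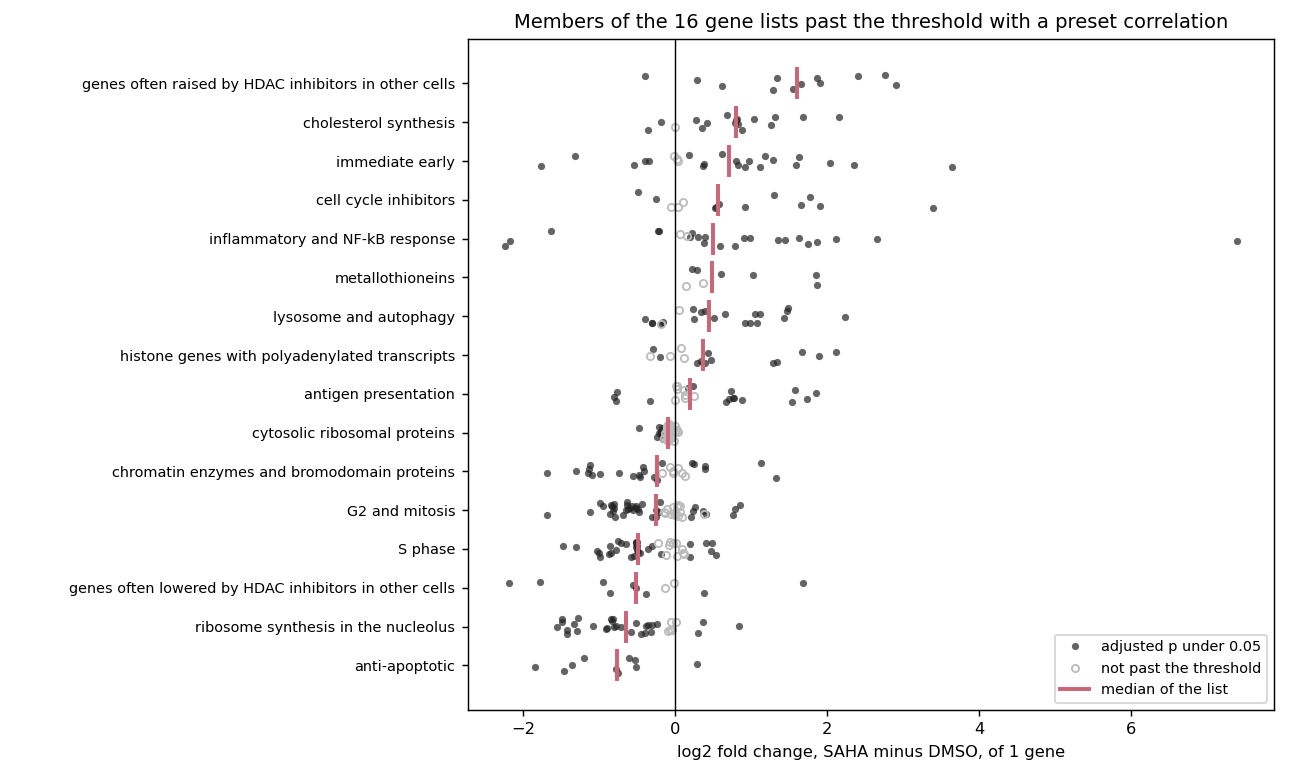
Log2 fold change of SAHA over DMSO (horizontal axis) of each measured gene of the 16 lists past the threshold in camera with a preset correlation, none of which passed with an estimated one. Filled points have an adjusted p under 0.05 in limma's test, open points do not, and red lines mark each list's median, from -0.77 for anti-apoptotic genes to 1.60 for genes often raised by HDAC inhibitors.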

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

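Centring on poly-A spike-ins and the ACTB covariate were chosen after results were seen. Probe sets that stand outside the gene-level comparison also changed with SAHA in limma's test over probe sets. Of the 2473 probe sets with no gene name, 515 were higher and 483 lower, of which 104 and 56 by at least 2-fold. Of the 1832 that name several genes, 296 were higher and 431 lower, of which 49 and 77 by at least 2-fold. They stand apart because the gene-level comparison does not use them, though the test over probe sets in place of genes does. The share changed was 40.4% and 39.7%, against 47.0% of probe sets that name 1 gene.

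The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes changed, higher, lower, and higher or lower by at least 2-fold, 1 of the 10 splits, the real one, gave as many (8764, 4457, 4307, 1075 and 810), and the highest of the other splits gave 0 in limma's test, with at most 372 genes at an unadjusted p under 0.05. For gene lists in camera with a preset correlation, 1 of the 10 splits gave as many as the real 16, and the highest other gave 8. Every other split mixes SAHA and DMSO arrays in both groups. The change between treatments then widens the spread within groups, which can by itself bring the gene counts to 0. Part of that change also stays in the difference between groups. The gene and list counts of the other splits are therefore no reference for chance.

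The ACTB 3' to 5' difference was smaller in the SAHA arrays, by 0.28 (that of GAPDH was larger, 0.06 against 0.03), and the 1885 genes changed by at least 2-fold go with it. RNA integrity or amplification was tested through that measure within the DMSO arrays. Replicates 1 and 3 differ by 0.32 in it, about as much as the groups. Of the 1885 genes, 6 (0.318%) differed between those 2 arrays by a share of at least 0.5 of their SAHA change, in its direction. These genes were called for a small spread within groups, which makes a low share likely in advance. The 28S control went the other way, from 10.39 to 10.60 in DMSO replicates 1 and 3 and from 10.49 to 9.97 between groups. An 18S control went the same way in both, from 12.17 to 11.94 and from 11.99 to 11.81. So did the GAPDH difference, from 0.036 to 0.043 and from 0.03 to 0.06. The test therefore does not decide whether RNA integrity or amplification is the source of the set. With the measure as a covariate a median share of 0.995 of the log2 fold change was left, and 1880 genes still passed. A linear effect of the measure is not decided by this, because the covariate is fitted on the spread within groups. These genes were called for a small spread, which makes a share near 1 likely in advance. The median standard error rose from 0.074 to 0.123 with the covariate. The covariate is partly confounded with the groups, and the treatment itself, which the design names, stays among the open explanations as untested.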

How the results depend on the processing

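Centring on poly-A spike-ins and the ACTB covariate were chosen after the data were seen. Of the 163 named genes called, 131 kept the call in each setting that measured them and 160 kept their direction. Reversed were ADAMTS6 (0.11), PDGFRA (-0.18) and ULBP2 (-0.10) in the second probe set, and ULBP2 (-0.07) without _x_at and _s_at probe sets. Relative to all genes, which centring cannot move, each of the 16 called lists kept its direction in each setting that tested it. The metallothionein list was not tested without _x_at and _s_at probe sets. The median of the cytosolic ribosomal proteins itself went from -0.10 to 0.06 with poly-A centring. With an estimated correlation 0 of the 16 lists kept the call, whereas fry called 28. Genes higher by at least 2-fold were 679 over genes with a mean of 7 or more, where fewer genes are tested. Genes lower were 2556 with poly-A centring, which shifts each gene's fold change by the same amount. With treat, a stricter question, 5290 genes changed by more than 1.2-fold (2759 higher, 2531 lower) and 654 rose and 408 fell by more than 2-fold. Over probe sets, of which there are more, 22850 changed (10949 higher, 11901 lower), 2446 and 2042 of them by at least 2-fold. With the ACTB covariate 6537 genes changed. Without 1 array, 8069 to 8486 genes changed, 4115 to 4332 were higher and 3952 to 4154 lower, 1069 to 1117 and 789 to 849 by at least 2-fold, with 16 to 17 lists.

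Same-numbered arrays did not deviate together (r = -0.126, -0.070 and -0.041 across genes), and 0 of 6 arrays correlated best with its own number. With the replicate block 8291 genes changed, 8131 of them shared with the 8764, and 16 lists passed. Levels near the floor of the scale, 2.72 to 2.78 in background probe sets, limit the fold changes of dim genes.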

Other observations

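The families below, the tests and simulations of level, except that by the mean of all arrays, and the tests of IFIT probe sets were chosen after results were seen. Genes were grouped by the letters that start their symbol, and the 189 families with at least 12 measured members were tested with camera at the preset correlation. Genes of the mitochondrial ribosome were lower with SAHA, with 37 of 48 MRPL genes lower and 2 higher, and 21 of 27 MRPS genes lower and 0 higher. In camera MRPL had an adjusted p = 8.80e-07 and MRPS one of 2.51e-05, against adjusted p = 0.923 for both with an estimated correlation. MRPL27 fell by 1.29 ± 0.05, MRPL15 by 1.27 ± 0.06, MRPS18B by 1.25 ± 0.07 and MRPS27 by 1.03 ± 0.05. Genes of TIMM proteins, which carry precursors across and into the inner mitochondrial membrane, were lower in 12 of 14, with TIMM9 at -1.29 ± 0.08. In other families too more genes were lower than higher, among them 24 of 37 DDX helicases, 10 of 12 SRSF splicing factors, 9 of 12 LSM proteins and 25 of 38 RBM proteins, each with an adjusted p = 0.923 with an estimated correlation. SRSF8 fell by 1.47 ± 0.10, SRSF4 by 1.16 ± 0.06 and DDX6, of mRNA decay, by 1.53 ± 0.06. Of 24 NUP symbols, mostly nuclear pore genes, 18 were lower, with NUP50 at -1.29 ± 0.07.

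Genes of intraflagellar transport, the traffic that builds cilia, were higher in 16 of 19 and lower in 0, with a mean of 0.83. IFT88 rose by 1.47 ± 0.05, IFT22 by 1.37 ± 0.06 and IFT172 by 1.17 ± 0.06. Of 36 CEP symbols, mostly centrosome genes, 22 were higher and 8 lower, with CEP19 at 2.51 ± 0.07 and CEP70 at 1.75 ± 0.05. Of 81 ATP symbols, a mixed group of ion pumps and ATP synthase subunits, 34 were higher and 4 lower. The copper transporters ATP7A (2.45 ± 0.12) and ATP7B (2.48 ± 0.07) and the calcium pump ATP2B4 (3.19 ± 0.10) rose. In all, 15 families passed and 0 did with an estimated correlation, where 8 of the 189 had an unadjusted p under 0.05 and the 15 had adjusted p-values of 0.804 to 0.923. The medians of these families kept their direction after centring on ribosomal protein genes and poly-A spike-ins, except that of RPL symbols, which went from -0.10 to 0.06 with poly-A centring. Fewer members were lower with poly-A centring, as in MRPL (20), MRPS (12), TIMM (5), SRSF (5), DDX (17), RBM (16) and NUP (10).

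Sorted by the mean of all 6 arrays, genes at log2 values of 6 to 7 were lower in 19.5% and higher in 30.1%, and genes at 11 and above lower in 36.5% and higher in 24.8%. Sorted by a DMSO array the mean change at 5 to 7 exceeded that at 10 and above by at least 0.359, but sorted by a SAHA array it was the smaller by 0.133 to 0.170, so the sign depends on which group sorts. The sorting array was left out of the change, and DMSO arrays alone gave -0.0297 in the same way. This argues against noise in the DMSO arrays as the source of the difference sorted by a DMSO array. Real changes alone can give that difference its sign, so the test does not bear on the pattern sorted by the mean. Hybridization spike-ins differed by -0.0836 ± 0.0262 (SE over 6 and 8 probe sets) between levels of 7 to 9 and 10 and above, where genes differed by 0.0472. This argues against a narrower scale of the SAHA arrays at those levels. No spike-ins were compared at the levels of 5 to 7 on which the pattern rests. Sorted by the mean, the difference was 0.136 ± 0.0156 (SE over genes), above the bound of 0.05 set before it was seen. Changes of the observed size simulated in 4 settings and made equal in distribution left at most 0.0375. That argues against equal distributions as the whole source for changes like those simulated. Neither this SE nor that of the spike-ins measures the spread between arrays, which limits both readings. The treatment and the floor of the scale were not tested.

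Interferon-induced genes moved apart, with IFIT1 at 2.96 ± 0.05 and ISG15 at 2.09 ± 0.05 and IFIT2 at -2.01 ± 0.11. Probes that match similar transcripts could give such a split. Both IFIT2 probe sets end in _at alone and both fell, the smaller fall being -0.838 ± 0.0958, which argues against this for IFIT2. For the rise of ISG15, measured only by a probe set ending in _s_at, shared probes stay open. For IFIT3 (-1.99 ± 0.13) and OASL (2.43 ± 0.06) there were 0 probe sets ending in _at or _a_at, so probes shared with similar transcripts and a response to the treatment cannot be told apart.

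Of the 161 genes with probe sets called in both directions, 1 had them at 2-fold each way. VPS36, of the ESCRT-II complex and chosen after its values were seen, was at 2.21 ± 0.12 in 1 of its 8 probe sets, the only one ending in _s_at, and at -0.37 to -1.55 in 6 others, while the eighth was at -0.05 ± 0.09.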
